A study of Homo sapiens with 6 samples.

How the data were processed

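RNA was extracted with TRIzol and libraries were made with the TruSeq RNA Library Prep Kit v2, per the labels' protocols. This kit does not mark strand. The deposited files hold raw counts per gene, 1 file per tumor. Per the submitters' processing notes, the tools named were bcl2fastq 2.17.1.14, STAR 2.5.2a and featureCounts 1.5.0-p1, with the genome build hg38. The annotation release, the settings for strand and multiply mapped reads, and the treatment of mouse reads in these xenograft libraries were not given in the sources used here. Reads shared between near-identical genes, such as those of the HLA family, may therefore be split or lost, and reads of an antisense pair cannot be told apart. Each file listed 60617 gene identifiers, of which 58542 were in GENCODE release 29 (GRCh38), used here for positions and biotypes, and 42335 were given a symbol. No count was seen in any library for 14133 identifiers, and 0 rows named no gene.

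Depth ranged from 12400782 to 27599159 counts per tumor, and both libraries of the 2-library set were deeper than the other 4. The smallest level that 3 counts stand for was 0.216, 0.242 and 0.109 CPM in anle138b replicates 1 to 3 and 0.189, 0.207 and 0.132 CPM in untreated replicates 1 to 3. Reads carry no molecular identifiers, so these floors and the exact intervals cover counting error only. The most abundant gene took 1.22% to 2.6% of counts, and mitochondrially encoded genes took 1.38% to 3.09%. Replicates were compared by a chi-square test of their counts before use. Its statistic per degree of freedom was 10.5 to 58.8, so no pair agreed within sampling noise and each library counted as 1 replicate. Groups came from the treatment label. Replicate numbers were given in listing order and pair no tumors.

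Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 20423. Libraries were scaled by TMM, and the quasi-likelihood F test (glmQLFit, glmQLFTest) was applied with treatment and naming set in the design, 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are treated over untreated, with standard errors derived from the F statistic, and the biological coefficient of variation was 12.8%. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. The interaction of treatment and naming set was tested in the same way with 2 residual degrees of freedom, all from the 4-library set. Gene lists, 30 in all, were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry beside it, on voom values from limma 3.58.1, two-sided. With an estimated correlation camera tests on the 3 residual degrees of freedom, so a modest list shift could hardly pass whatever its correlation. The MHC class II list, with an estimate of 0.004, went from an unadjusted camera p of 3.27e-28 to 0.0014. Of 751 list entries, 750 matched an identifier. The count adjusted over the list alone is Benjamini-Hochberg within that list.

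The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest log2 fold changes among called genes with a symbol, an average log2 CPM of at least 1 and every treated library on the same side of every untreated library within each naming set. It also took each measured member of the MHC class II list, and up to 4 members of each other list with the smallest p. Some genes that the rule took, and 2 of the 30 lists, are not reported here. Genes named outside this rule are said to be chosen after their values were seen. The MHC class II list was drawn up with knowledge of the series title.

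The fits were tested on simulated data. Counts for 20423 genes were drawn from the fitted means, dispersions and library sizes of the 6 tumors, with 200 genes changed. The changed genes were taken from those with a mean of at least 2 CPM, so the recovery shares do not cover lower genes. Among the 20008 that passed the filter, edgeR recovered 22%, 88%, 100% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 18 false calls, 10.4% of its calls. Without the set term the shares were 0%, 38%, 78% and 94%, with 0 false calls. The 10.4% of false calls with the term lies above the threshold of 0.05. Of 30 simulated lists, camera called the 1 list that held raised genes and 0 of 29 random lists. The simulated genes varied independently. These lists therefore do not test camera where members vary together, and the measured lists had estimated correlations of up to 0.933. A simulated interaction was not included, and 0 genes were called for it.

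Alternatives were no set term, DESeq2 size factors, upper-quartile scaling and library size alone, no low-count filter, a filter of 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma voom, the 4-library set alone, protein-coding genes alone, no mitochondrially encoded genes, glmTreat against 1.5-fold, and leaving out each library in turn with and without the set term. With the set term kept, leaving out 1 library of the 2-library set lets the term fit the other exactly. Both such fits then draw the treatment effect from the 4-library set and are not checks apart from it. Other tests of the interaction were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.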

Results

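Gene expression was measured by RNA sequencing in 6 tumors grown as xenografts from WM983-B, an established human melanoma cell line. The tumors formed 2 groups of 3, anle138b and untreated. Anle138b is a diphenyl-pyrazole small molecule that binds oligomers of aggregating proteins and was given systemically. The sample titles fell into 2 naming sets, and each set held both groups: a 4-library set with 2 treated and 2 untreated tumors, and a 2-library set with 1 of each. What the naming sets stand for was not given in the sources used here. Gene counts summed to 13874820, 12400782 and 27599159 in anle138b replicates 1 to 3, and to 15865560, 14464593 and 22768826 in untreated replicates 1 to 3. The third replicate of each group belonged to the 2-library set. A count of 0 allowed a level of up to 0.242 CPM in the shallowest library and 0.109 CPM in the deepest, for counting error only. Nothing in the labels says that the tumors came from separate animals, so p-values measure the spread between these libraries.

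The question named in the series title is what happens to MHC class II expression in melanoma under this treatment. The genes that rose most after anle138b were led by this class. HLA-DRA, the alpha chain of the class II molecule HLA-DR, rose by a log2 fold change of 6.72 ± 0.23 (SE, n = 3 per group; adjusted p = 2.84e-06, edgeR quasi-likelihood test). The gene lies on chromosome 6 at 32439842 to 32445046 (GRCh38) and had 526, 445 and 4225 counts in the treated tumors, against 8, 1 and 36 in the untreated tumors. CIITA (chromosome 16, 10866222 to 10943021), the transactivator that switches on class II genes, rose from 10.1 ± 1.51 CPM to 34.3 ± 3.42 CPM (SD, n = 3), a log2 change of 1.77 ± 0.12 (adjusted p = 0.00023). CD74 (chromosome 5, 150401637 to 150412929), the invariant chain that escorts class II molecules, rose from 48.3 ± 27.2 CPM to 314 ± 50.03 CPM (log2 change 2.82 ± 0.26, adjusted p = 0.001).

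Of the 21 genes in the MHC class II list, 17 passed the low-count filter, and of these 11 rose, 0 fell and 6 did not pass the test. The count adjusted over the list alone was the same, 11 raised and 0 lowered. The list was chosen with the series title in view, so it is not independent evidence of direction. HLA-DPB1, HLA-DRB1 and HLA-DRB5 rose by 4.75 ± 0.24, 3.78 ± 0.29 and 3.68 ± 0.24 on the log2 scale. HLA-DOA, HLA-DPA1 and HLA-DQB1 rose by 2.92 ± 0.32, 2.36 ± 0.12 and 1.96 ± 0.31. HLA-DMA and HLA-DMB, whose product loads peptides onto class II molecules, rose by 1.77 ± 0.21 and 0.95 ± 0.18. The members that did not pass included the DNA-binding cofactors of CIITA, with log2 changes of 0.18 for RFX5, 0.14 for RFXAP and 0.03 for RFXANK. The lysosomal proteases CTSS and LGMN had changes of 0.04 and -0.13, and HLA-DOB one of 0.32. The median member changed by 1.77, and the list was called by camera (adjusted p = 9.80e-27), with adjusted p = 0.042 with an estimated correlation and adjusted p = 0.0024 by fry. HLA genes share near-identical sequence, and HLA-DPA1 overlaps HLA-DPB1 on the opposite strand in a library type that does not mark strand, so the split of reads among them is uncertain. The call of HLA-DOA was lost without anle138b replicate 3 (adjusted p = 0.0903), that of HLA-DQB1 without replicate 1 or 3 of either group (adjusted p up to 0.32), and that of HLA-DMB without any library but anle138b replicate 2 (adjusted p up to 0.286), while the log2 change of HLA-DRB1 was 4.76 without anle138b replicate 3 and 4.77 without untreated replicate 3.

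**Figure D1:**
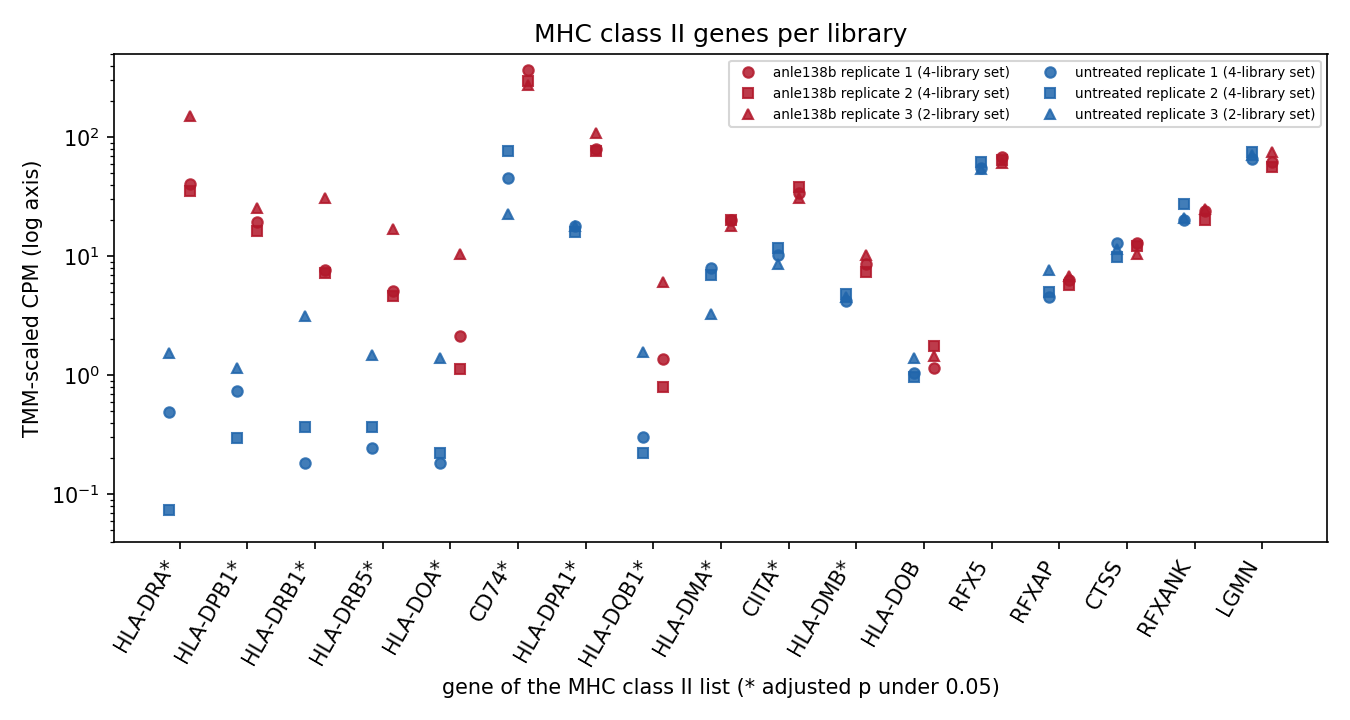
TMM-scaled CPM on a log axis for the 17 measured genes of the MHC class II list, with 1 point per library, red for anle138b, blue for untreated, and a triangle for the 2-library set; an asterisk marks the 11 genes that passed the test. Treated libraries lie above untreated libraries of their own set for each of the 11 genes, from 35.54 to 149.5 CPM against 0.07407 to 1.527 CPM for HLA-DRA. Treated and untreated libraries of each set were likewise apart for all 215 called genes.

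Outside this list, DMTN, which encodes the actin-bundling protein dematin, rose by 5.33 ± 0.23 on the log2 scale, from 0.5846 ± 0.3755 to 24.5 ± 4.96 CPM (SD, n = 3; adjusted p = 9.50e-06). CYP1A1, a cytochrome P450 of xenobiotic metabolism, rose by 4.20 ± 0.55 (adjusted p = 0.00671). Its counts were 47, 73 and 879 in treated against 11, 10 and 13 in untreated tumors. Its log2 change was 2.73 without anle138b replicate 3 and 2.74 without untreated replicate 3. Both of these fits draw the treatment effect from the 4-library set, so they are the same check. SERTAD4, the protocadherin gene DCHS2 and DKK3, a secreted modulator of Wnt signalling, rose by 3.41 ± 0.31, 3.04 ± 0.45 and 2.98 ± 0.24. RMEL3, a melanoma-associated long non-coding RNA that overlaps ACTBL2 on the opposite strand, rose by 3.52 ± 0.39. Without anle138b or untreated replicate 3 the changes of SERTAD4 were 2.56 and 2.57, those of RMEL3 2.39 and 2.40, and those of LUZP4, among the lowered genes, -1.14 in both fits. Among the genes that fell, the axon guidance gene SLIT1 changed by -2.78 ± 0.41, from 8.10 ± 3.78 to 1.23 ± 0.537 CPM (adjusted p = 0.0129). HHATL, the transmembrane protease gene TMPRSS3 and the sodium channel gene SCN9A changed by -2.60 ± 0.29, -2.30 ± 0.34 and -1.94 ± 0.32. NELL1, ADGRV1, SEMA6B and FBLIM1 changed by -1.93, -1.76, -1.69 and -1.67. LINC02552, LUZP4 and LINC01537 changed by -1.80, -1.77 and -1.76.

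Over all genes, 215 of 20423 tested changed, 134 raised and 81 lowered, and 177 of the 215 were protein-coding. In simulated counts 10.4% of the calls by the same fit were false, more than the threshold of 0.05 allows for. At least 2-fold changes were seen in 77 raised and 48 lowered genes. The fit included a term for the naming set, and without that term 9 genes were called, 9 raised and 0 lowered, with 800 at an unadjusted p below the threshold. Those 9 included HLA-DPA1, HLA-DPB1, CIITA, DMTN and OCA2, and 3 of the 11 raised MHC class II genes were among them. HLA-DRA, CD74 and HLA-DRB1 were not called without the term (adjusted p = 0.0748, 0.109 and 0.687), while all 215 genes kept their direction and 183 of them an unadjusted p under 0.05. With the set term kept, the count was 143, 392 and 89 without anle138b replicate 1, 2 or 3, and 136, 151 and 116 without untreated replicate 1, 2 or 3. The calls of HHATL, TMPRSS3, SLIT1, SCN9A, NELL1, SEMA6B, FBLIM1, LUZP4, DCHS2 and both long intergenic RNAs were lost without either library of the 2-library set, with adjusted p from 0.0749 to 0.616 at the highest, and that of RMEL3 without its treated library (adjusted p = 0.0968). Calls were also lost without untreated replicate 1 for SCN9A, LUZP4, DCHS2 and LINC01537, and without untreated replicate 2 for SEMA6B, FBLIM1 and LINC01537.

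The naming sets were compared because 53.8% of the variance lay on a first principal component that separated them, and 17% on a second that separated treated from untreated tumors. In the 4-library set alone, with 2 tumors per group, 92 genes changed, 73 raised and 19 lowered. HLA-DRA changed there by 6.94, CIITA by 1.72 and CD74 by 2.45. In the 2-library set the log2 CPM of the treated tumor exceeded that of the untreated tumor by 6.51 for HLA-DRA, 1.84 for CIITA and 3.59 for CD74, values of single libraries with no test. Of the 92 genes, 89 moved the same way in the 2-library set, or 96.7% (exact 95% interval 90.8% to 99.3%). This interval takes the genes as independent, though class II genes among them rose together. All were read in 1 pair of tumors, so it does not measure the spread between tumors. Among the 19791 genes not called in the 4-library set, 50.7% moved the same way. The treatment effect differed between the sets for 0 genes by edgeR, with 1345 at an unadjusted p under 0.05, by limma for 0 genes, and by DESeq2 for 31. In the DESeq2 fit the rise of CYP1A1 was larger in the 2-library set (adjusted p = 0.0431, against adjusted p = 0.357 by edgeR). Among those 31, chosen after their values were seen, were the small nuclear RNAs RNU4-1 and RNU4-2, the small nucleolar RNA SNORA73B and the mitochondrial MT-CYB, each with its highest count in untreated replicate 3, such as 14219 against 3450 to 8293 for RNU4-2. In that library 0.54% of counts were of the miscellaneous RNA biotype, against 1.28% to 2.69% in the other 5, and 3.09% were mitochondrially encoded, against 1.38% to 2.81%.

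**Figure D2:**
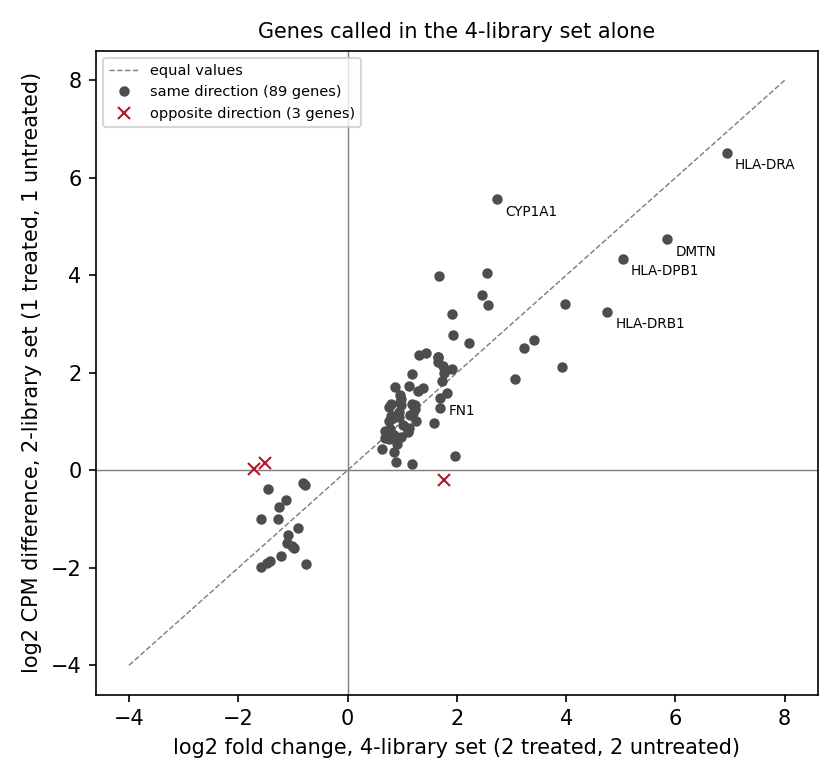
Each point is a gene called in the 4-library set, with its log2 fold change there on the x axis and the log2 CPM difference between the single treated and untreated tumor of the 2-library set on the y axis; the dashed line marks equal values. Of the 92 genes, 89 lie on the same side of 0 on both axes, with HLA-DRA at 6.94 and 6.51.

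FN1, the gene of fibronectin and among the most abundant transcripts in these tumors, rose by 1.62 ± 0.15 on the log2 scale, from 3215 ± 311 to 9973 ± 1854 CPM (SD, n = 3; adjusted p = 0.001). It was the 1 gene of 27 measured in the extracellular matrix list that rose; 0 fell and 26 did not pass, with 3 raised and 0 lowered when adjusted over the list alone. MMP2, a matrix metalloproteinase, had a change of 0.82 ± 0.18 (adjusted p = 0.0815). The treatment of mouse reads was not given, so host reads counted for FN1 and MMP2 cannot be excluded. The matrix list was called upward by camera with a median change of 0.16 (adjusted p = 1.10e-05), a call lost with adjusted p = 0.968 with an estimated correlation. The latter test rests on 3 residual degrees of freedom, so such a loss does not show that members varied together. SNAI2, a transcription factor of the neural crest and of epithelial-mesenchymal transition, rose by 1.40 ± 0.13, from 57.8 ± 7.26 to 154 ± 35.3 CPM (adjusted p = 0.00087). In the dedifferentiated melanoma list 1 of 28 genes rose and 0 fell, or 4 and 1 when adjusted over the list alone. Its camera call (median 0.15, adjusted p = 0.00274) was lost with adjusted p = 0.968 with an estimated correlation.

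OCA2, which encodes a melanosomal membrane transporter, rose by 1.88 ± 0.14, from 65.3 ± 9.98 to 239 ± 29.3 CPM (SD, n = 3; adjusted p = 0.0004). It was the 1 gene of 24 in the melanocyte differentiation list that rose, with 0 lowered and 23 not called, or 3 raised and 3 lowered when adjusted over the list alone. The pigment enzymes TYRP1 and DCT had changes of 1.42 ± 0.30 and 0.42 ± 0.12 that did not pass over all genes (adjusted p = 0.0692 and 0.228). TYRP1 was called in the 4-library set alone, with a log2 change of 1.98 (adjusted p = 0.000938), against a difference of 0.29 in the 2-library set, and DESeq2 called its interaction with the naming set (adjusted p = 7.37e-05, against adjusted p = 0.325 by edgeR). The list's median was 0.03, and camera made no call (adjusted p = 0.51).

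Genes of antigen presentation by MHC class I showed no call, 0 of 22. Their median change was 0.11, with HLA-E at 0.42 ± 0.11 (adjusted p = 0.159) and HLA-B at 0.35 ± 0.12 (adjusted p = 0.34). Camera called the list upward (adjusted p = 0.0064), a call lost with adjusted p = 0.968 with an estimated correlation. With 3 residual degrees of freedom in that test, the loss cannot be put down to correlated members alone. In the cell cycle list 0 of 42 genes passed, and its camera call (median 0.10, adjusted p = 0.00086) was likewise lost with adjusted p = 0.968 with an estimated correlation. Other splits of the 6 tumors into 3 and 3 gave up to 17 lists called by camera with the preset correlation, against 6 for treatment. The split with 17 put both tumors of the 2-library set on 1 side, and splits with 1 on each side gave up to 16. The interferon gamma response list had 1 of 20 genes raised, SECTM1, a secreted and transmembrane ligand (log2 change 3.94 ± 0.59, adjusted p = 0.013). SECTM1 rested on 10, 11 and 74 counts in treated against 3, 0 and 2 in untreated tumors, and its call was lost without anle138b or untreated replicate 3 (log2 changes 2.95 and 2.96, adjusted p = 0.32 and 0.237), its log2 change being 5.07 without untreated replicate 1. That list's median was 0.06 (camera adjusted p = 0.397). In the type I interferon list 0 of 37 genes passed (median -0.09, adjusted p = 0.0816), and camera called it downward with the stricter filter (adjusted p = 0.0326) and without anle138b replicate 1 (adjusted p = 0.0173). It had adjusted p = 0.968 with an estimated correlation.

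Single members of 3 further lists changed. CRYAB, the small heat shock protein αB-crystallin, fell by 1.17 ± 0.14 on the log2 scale (adjusted p = 0.00418), 1 of 26 genes in the heat shock list. CDH1, the gene of E-cadherin, fell by 1.16 ± 0.21 (adjusted p = 0.0355), 1 of 6 measured epithelial genes, a call lost without untreated replicate 2 (adjusted p = 0.0672). Its change was -0.77 in the 4-library set alone against -1.92 in the other pair, and DESeq2 called its interaction with the naming set (adjusted p = 0.0407, against 0.357 by edgeR). LUM, the gene of the proteoglycan lumican, rose by 0.70 ± 0.12 (adjusted p = 0.0249), 1 of 15 fibroblast and pericyte genes, a call lost without replicate 1 or 3 of either group (adjusted p up to 0.174). Reads of the mouse host counted for LUM cannot be excluded. Camera called none of these 3 lists in all 6 tumors (adjusted p = 0.66, 0.224 and 0.305), but called the epithelial list downward with the stricter filter (adjusted p = 0.0311) and the fibroblast list upward without anle138b or untreated replicate 1 (adjusted p = 0.00691 and 0.0349). Both had adjusted p = 0.968 with an estimated correlation. No member passed over all genes by edgeR in the lists of autophagy and lysosome (0 of 45), the unfolded protein response (0 of 33) and Ras-MAPK output (0 of 18). Camera adjusted p was 0.48, 0.305 and 0.264. When adjusted over the list alone, 1 gene of the unfolded protein response and 4 of Ras-MAPK output were raised. The lists of NF-kB and cytokine targets, p53 and apoptosis, hypoxia, oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, T cell co-stimulation, ribosomal proteins and histones had 0 members called by edgeR over all genes. Their median changes were from -0.25 to 0.11 and camera adjusted p from 0.0816 to 0.965. When adjusted over the list alone, NF-kB and cytokine targets had 1 raised and 1 lowered gene, and p53 and apoptosis 2 raised and 1 lowered. The mitochondrially encoded list had a median of -0.25 and was downward by camera (adjusted p = 0.212). By subset, camera called it in both directions. It was upward in the 4-library set alone (adjusted p = 0.000814) and without anle138b or untreated replicate 3 (0.000628 and 0.000314). These upward calls draw the treatment effect from the same tumors. It was downward without anle138b replicate 2 (0.000296) and without untreated replicate 1 (1.53e-10). Its members had an estimated correlation of 0.933, and the list had adjusted p = 0.968 with an estimated correlation. Oxidative phosphorylation, hypoxia and histones were called upward by camera without replicate 2 of either group, with adjusted p from 2.84e-07 to 0.0158, and each had adjusted p = 0.968 with an estimated correlation.

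Markers of other cell types were measured beside these groups. These are human genes in xenografts, and the treatment of mouse reads was not given. Their levels therefore cannot show how many mouse cells of the host were present. The myeloid list had 0 of 13 genes called and a median of -0.10 (camera adjusted p = 0.899). The lymphocyte list had 0 of 3 (median -0.43, adjusted p = 0.264), and the endothelial list 0 of 10, or 1 lowered when adjusted over the list alone (median 0.03, adjusted p = 0.929). The adipocyte and muscle list had 0 of 9 (median 0.10, adjusted p = 0.899), and the erythrocyte and platelet list 0 of 3, with a median of -0.24, a mean of 0.09 and a camera direction upward (adjusted p = 0.879). The skeletal muscle transcripts CKM and TNNT3, below the low-count filter and chosen after their values were seen, were at 10.6 and 6.21 CPM in anle138b replicate 2 and at no more than 0.483 and 0.22 CPM in each of the other 5 libraries. Without that tumor 392 genes were called, 208 raised and 184 lowered, with 212 of the 215 calls kept.

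**Figure D3:**
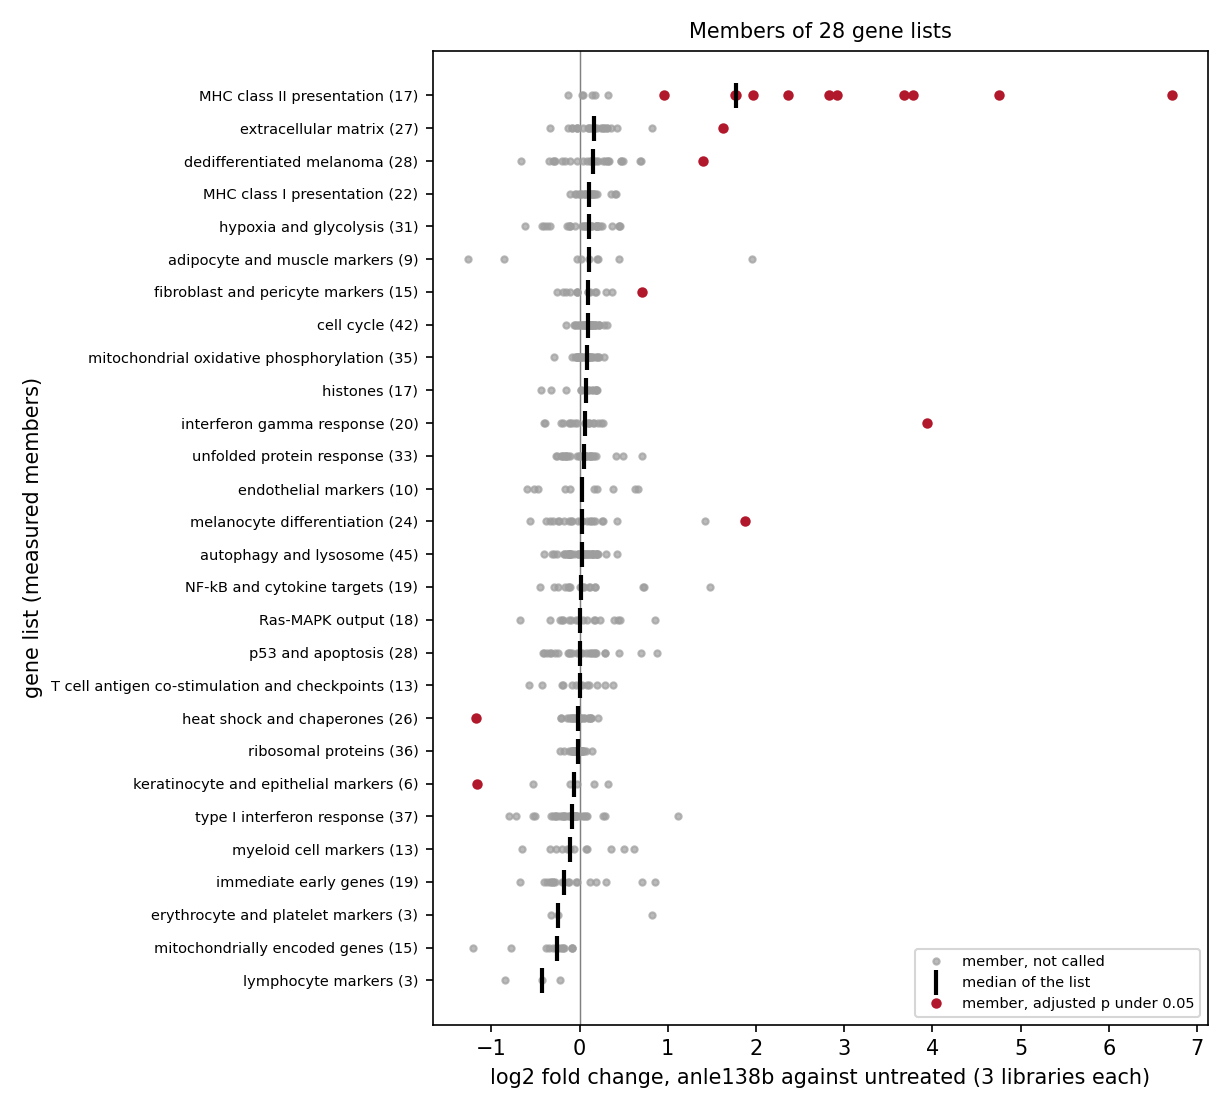
Log2 fold change of anle138b against untreated for each measured member of 28 of the 30 gene lists, sorted by list median, with the number of measured members in parentheses; red points passed the test over all genes, grey points did not, and the black bar is the median. The MHC class II list has a median of 1.77, and the other 27 medians lie between -0.43 and 0.16.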

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

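All alternatives were chosen before the data were examined, except the DESeq2 and limma tests of the interaction and the fits of genes chosen after their values were seen. The set term decided how many genes passed. Without it 9 genes changed (9 raised, 0 lowered) against 215 (134 raised, 81 lowered), and in the 4-library set alone 92 did (73 raised, 19 lowered); the standard error of the 215 genes grew from a median of 0.154 to 0.258, while their log2 fold change moved by a median of 0.0138. With library size alone the lowered count was 129. With no low-count filter 46484 genes were tested and 754 changed (354 raised, 400 lowered). The cause was not tested for either setting. The DESeq2 Wald test called 412 (231 raised, 181 lowered), with 206 of the 215 among them, and glmTreat against 1.5-fold, a stricter question, called 58 (50 raised, 8 lowered). DESeq2 size factors, upper-quartile scaling, the stricter filter, voom, protein-coding genes alone and leaving out mitochondrial genes gave 194 to 275 changed genes. In all settings with the set term and all 6 tumors, 0 of those of the 215 genes that were tested turned direction. The stricter filter tested 182 of them and protein-coding genes alone 177. Leaving out 1 library with the set term gave 89 to 392 changed genes, 69 to 208 raised and 20 to 184 lowered. The fits without a tumor of the 2-library set draw the treatment effect from the 4-library set, so they repeat that check. Leaving out 1 library without the set term gave 0 to 14 changed genes, 0 to 14 raised and 0 lowered, from fewer tumors. By edgeR the number at an unadjusted p under 0.05 was then 616 to 1660. Of the 50 called genes that the naming rule or later choice took, 27 were called in all 6 fits without 1 library, 28 in the 4-library set alone, 8 without the set term, and each held in every fit by another scaling, filter, the DESeq2 Wald test, voom or without mitochondrial genes that gave it an adjusted p.

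Camera called 6 lists, 1 with an estimated correlation and 1 by fry, in both cases MHC class II, and 10 without anle138b replicate 2. An estimated correlation leaves camera 3 residual degrees of freedom, so modest list shifts could hardly pass it. In the 4-library set alone it called MHC class II, cell cycle, mitochondrially encoded genes upward (adjusted p = 0.000814, against downward and 0.212 in all 6 tumors, and called downward without anle138b replicate 2 or untreated replicate 1) and immediate early genes downward (0.0225), and not the MHC class I, dedifferentiated melanoma and matrix lists (0.202, 0.202 and 0.122). Oxidative phosphorylation was called upward with library size alone (0.0424), and without anle138b or untreated replicate 2 (2.84e-07 and 4.36e-05), as were hypoxia (0.0158 and 2.91e-05) and histones (0.000615 and 0.000393) in the latter 2 fits. Immediate early genes were also called downward without anle138b or untreated replicate 3 (0.0211 and 0.0171). The interaction was called for 0 genes by edgeR and limma and 31 by DESeq2; the cause was not tested.

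Direction turned for uncalled genes near 0 and for genes whose level differs between the sets. RFXANK, at 0.029, was -0.096 in the 4-library set alone and ranged from -0.097 to 0.194 over the fits without 1 library, and from -0.043 to 0.175 where the set term was left out too. CTSS, at 0.045, ranged from -0.076 to 0.154 and from -0.034 to 0.177. Without the set term and 1 library, the ranges were -0.67 to 1.94 for EGFR, -0.081 to 1.69 for BMF, -0.229 to 1.15 for VCAN, -0.463 to 1.9 for KDR and -1.92 to 4.99 for CCL18, each lowest without anle138b replicate 3. They were -3.1 to 0.191 for LUZP4, -1.27 to 0.035 for IFI44L and -1.36 to 0.241 for IFI27, each highest without untreated replicate 3. In those fits the sets are unequally spread over the groups. No paired analysis was possible because the replicate numbers only name the tumors. Groups of 3 give 10 splits, so no share of splits under 0.05 could be reached, and the 4 shallower libraries set a floor of 0.189 to 0.242 CPM.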

Other observations

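SLC1A4, MFSD12, TEKTIP1, HMG20B, CYGB, ALDH1A3, CD300LF, HLA-DRB6, CCL18, DSP, LIN28B, AHRR and NQO1 were chosen after their values were seen, and so were the tests of leukocyte markers, of shared HLA reads and of the naming sets; the tests of interferon gamma targets, of other aryl hydrocarbon receptor targets and of NRF2 targets were chosen before their results were seen. SLC1A4, a neutral amino acid transporter, went from 91.9 ± 12.7 to 337 ± 16.7 CPM (SD, n = 3; log2 change 1.88 ± 0.12, adjusted p = 0.00011, edgeR). MFSD12, a cysteine importer of lysosomes and melanosomes, rose by 1.87 ± 0.16, and TEKTIP1 and HMG20B on the opposite strand by 2.21 ± 0.19 and 1.32 ± 0.15. TEKTIP1 lies wholly within MFSD12 and HMG20B overlaps it in part, and reads of the shared stretches cannot be assigned to a strand. CYGB, the globin cytoglobin, and ALDH1A3, an enzyme of retinoic acid synthesis, rose by 1.97 ± 0.10 and 1.27 ± 0.10. CD300LF, an immune receptor gene, rose by 1.10 ± 0.14, and HLA-DRB6, a class II pseudogene, by 2.82 ± 0.30. Each of these 8 genes was higher in all 3 treated tumors than in the untreated tumors of its own set. All 215 called genes lay on 1 side in this way, so this adds nothing particular to these genes.

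The 2 naming sets differed in 3157 genes, 1699 higher and 1458 lower in the 2-library set. Over 4-fold differences were uneven, with 272 genes higher and 55 lower. Of all genes, 45 were at 5 CPM or more in both tumors of the 2-library set and under 0.5 CPM in all 4 others, and 0 showed the reverse. DSP, which encodes the desmosomal protein desmoplakin, was at 77.8 and 70.4 CPM against at most 0.432 CPM, and LIN28B, an RNA-binding regulator of let-7, at 19.6 and 18.9 CPM against at most 0.126 CPM. No gene met the same limits between treated and untreated tumors (0 in either direction). Each of these groups spans both sets, which makes the limits harder to meet. HLA-DRA, at 35.54 CPM or more in treated tumors, was at 1.527 CPM in untreated replicate 3. DMTN, at 20.69 CPM or more in treated tumors, was at 1.018 CPM there. CCL18, called as raised by 1.56 ± 0.22, was at 26.4 and 8.82 CPM in the 2-library set and under 1 CPM in the other 4 tumors, and its call was lost without anle138b or untreated replicate 3 (adjusted p up to 0.472).

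The first pattern weighed is the rise of MHC class II transcripts. Leukocytes in the treated tumors would bring their other transcripts. The CPM of 24 human leukocyte markers, picked for an untreated mean under 1 CPM, was summed. Its treated to untreated ratio was 0.886 (95% interval 0.699 to 1.12) in the 4-library set and 0.639 (0.527 to 0.775) in the other. These intervals cover counting error only, and the second ratio sets 1 tumor against 1. The more abundant markers LYZ (17.9 ± 7.71 to 23.2 ± 6.42 CPM) and MRC1 (7.16 ± 2.48 to 11 ± 5.24 CPM) were not called. Their log2 changes were 0.35 and 0.62, with upper 95% limits of 1.003 and 1.39. A rise of reads assigned to human leukocyte genes as a group was thus not seen. Leukocytes of the host would be mouse cells, and the treatment of mouse reads was not given, so these counts cannot decide on them. Reads shared among HLA genes do not account for CIITA and CD74, whose lower 95% limits of the log2 change were at least 1.49. Induction by interferon gamma would also raise its direct targets, yet 8 of them, with IRF1, GBP1, TAP1 and NLRC5 included, had a median log2 change of 0.081, against 1.77 for CIITA. A response of the melanoma cells to anle138b may explain the rise, as a hypothesis from these same 6 tumors, and whether it runs through CIITA was not tested.

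The second pattern is the joint rise of CYP1A1, AHRR, the repressor of the aryl hydrocarbon receptor (log2 change 2.33 ± 0.39, adjusted p = 0.0234), and NQO1, a quinone reductase (1.48 ± 0.14, adjusted p = 0.00098). A general NRF2 response of the size of the NQO1 rise was not seen, as 14 other NRF2 targets had a median change of 0.046 against 1.48 for NQO1. Of these 14, 11 were above 0 and 0 were called. TXNRD1 at 0.46 and SLC7A11 at -0.25 had an unadjusted p under 0.05 by edgeR. NFE2L2, the gene of NRF2 itself, is counted below among the receptor targets. A smaller NRF2 response is not excluded by these values. A rise in the 2-library set alone is argued against for CYP1A1 and NQO1. Both were called in the 4-library set alone (log2 changes 2.73 and 1.38, adjusted p at most 0.017 by edgeR). AHRR rose there by 1.91, at 1.53 and 2.00 CPM in treated against 0.67 and 0.22 CPM in untreated tumors. At these low levels it was not called (adjusted p = 0.26 by edgeR), so for AHRR the question stays open. A difference in size stays open for CYP1A1, at 5.56 in the other pair. The smallest interaction adjusted p over the 3 genes was 0.357 by edgeR, and that of CYP1A1 was 0.0431 by DESeq2. Activity of the aryl hydrocarbon receptor, for which CYP1A1 is the classical target, is a candidate explanation: CYP1B1 and TIPARP, other direct targets, had changes of 1.27 ± 0.41 and 0.45 ± 0.15, with unadjusted p-values of at most 0.0122 (adjusted p = 0.279 and 0.292), but of 0.49 and 0.21 in the 4-library set alone (adjusted p = 0.89 and 0.741) against 2.09 and 0.91 in the other pair, while of 6 measured targets 4 were above 0 (NFE2L2 0.41, unadjusted p = 0.00228, and ABCG2 0.40 among them), STC2 and SLC7A5 were at -0.41 and -0.34, and 0 were called, with 3 at an unadjusted p under 0.05 by edgeR. The AHRR call was lost without untreated replicate 2 or replicate 3 of either group, with adjusted p up to 0.288. AHRR overlaps PDCD6 on the same strand, and CYP1B1 overlaps RMDN2 on the opposite strand, among other genes. At treated means of 2.31 CPM for AHRR and 1.86 CPM for CYP1B1, the assignment of reads in shared stretches is uncertain.

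The third pattern is the fall from 215 to 9 called genes without a set term. For an offset of expression between the sets that inflates the error, the shift of the log2 changes cannot decide. It was a median of 0.0138 over the 215 genes, but equal numbers of treated and untreated tumors in each set fix this by design. The median standard error of these genes grew from 0.154 to 0.258, and the sets differed in 3157 genes. In the simulated counts, which held set differences, leaving out the term cut recovery from 88% to 38% of genes changed by 1 on the log2 scale. A set offset can therefore lose calls in this way, and whether anything else added to the fall was not tested. Whether the single pair of the 2-library set drove the calls was not decided for most of them. In the 4-library set alone 83 of the 215 genes were also called, and so did not need that pair, but for the rest it stays open. The 96.7% of genes called in the 4-library set that moved the same way in the pair covers only genes called without it.

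Splits of the 6 tumors into 3 and 3 number 10, too few for a share under 0.05. The real split gave 215 genes, 134 in the larger and 81 in the smaller direction. The highest of the other splits gave 0 in each case, so 1 of the 10 splits gave as many. The other splits mix treated and untreated tumors, so a treatment effect adds to their error. Their counts of 0 therefore do not measure what chance would give. For the gene lists, the real split gave 6 by camera with the preset correlation and the highest other split 17, and 9 of the 10 splits gave at least 6. The split with 17 put both tumors of the 2-library set on 1 side. Among other splits with 1 of these tumors on each side, the counts ranged from 5 to 16. Splits that call more lists than treatment does point to a structure of the samples, in that gene groups vary together between tumors.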
